A study of Mus musculus with 48 samples.

How the data were processed

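The 48 samples were mouse embryonic fibroblasts on a C57BL/6 background, from wild-type and knockout lines named for XBP1, ATF4, ATF6a and ATF6b. Cells were left untreated or given 2 ug/mL tunicamycin for 12 h or 24 h, in 2 independent experiments per group, which made 24 groups of 2 arrays. Per the labels, total RNA was isolated with a mirVana kit and 75 ng of it was labelled with Cy3 by the Low Input Quick Amp method, with 1 array per sample. Each of the 4 mediators has its own wild-type line. Whether these lines come from littermates is not given in the sources used here.

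The arrays are an Agilent one-colour design with 55681 probes at 59305 non-control spots and 3671 control spots, in 384 rows and 164 columns, with probe coordinates on mouse build mm9. Per the file headers, the spot intensities were read with Agilent Feature Extraction 10.7.1.1, which subtracts background and removes spatial trends within an array, with no scaling between arrays. The authors also deposited values that are log2 of the same processed signals, quantile normalized over the 48 arrays and rounded to 1 decimal. That scale was found from the values themselves, since all columns share 1 distribution with a median of 4.2, and the software used for it is not given in the sources used here. The scanner files were used for all main values and the deposited values for an alternative.

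Processed intensities were put on the log2 scale and shifted to the 75th percentile of the non-control probes of each array, so values are relative to that percentile of their own array and a change shared by most transcripts cannot be seen. Spots that the scanner software marked as non-uniform or as population outliers were left out, and the log2 values of replicate spots of a probe were averaged. A probe was tested if it was well above background on both arrays of at least 1 group, which left 34583 probes. The brightest tested probe stood for each gene, giving 25169 features: 14782 matched to RefSeq genes, 3393 named by a genomic interval (of 4607 on the array) and 6994 with other names. Gene symbols were matched through the RefSeq accessions of the probes to RefSeq genes of a later mouse assembly, which was also used to find neighbouring genes.

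Group means were fitted with limma 3.58.1 in R 4.3.3 (with data.table at version 1.17.8 and statmod at 1.5.0) over 24 groups, with moderated t tests and adjustment by the Benjamini-Hochberg method over all features of a comparison, and an adjusted p under 0.05 counted as passed. All adjusted p values of genes are from these limma fits. The comparisons were tunicamycin against untreated at each time over the wild-type lines, 24 h against 12 h, knockout against wild type in untreated cells, and the dependence of the response on each mediator, which is the interaction of genotype and treatment. A moderated F test compared the response among the wild-type lines. The comparisons, groups, tests, gene-naming rule and alternatives of the 48-array analysis were chosen before the data were examined.

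The set of 37 arrays, with its mask and its own alternatives, was chosen after seeing the data. It leaves out the 8 arrays of a dim hybridisation run, 1 partly failed array and 2 libraries whose targeted genes went against their labels. In it 9 treated groups hold 1 array, assumed to vary like the other groups, and ATF6b wild type at 24 h holds none. Some arrays have patches where all spots lost or gained signal. To mask them, each bright spot's log2 value was set against its median over the arrays and centred per array, with single residuals limited to 2. Spots were left out where the mean residual in a window 11 spots wide, holding at least 10 bright spots, was above 0.7 in size. A limit of 1 was tried first and lowered after some of the largest differences between lines were seen to lie in patches. The mask took a median of 0.0540% of the spots of these 37 arrays and at most 7.47% (4429 spots), and some small patches may remain. The median residual SD was 1.26 on the 48 arrays (24 residual degrees of freedom, prior 3.55) and 0.454 on the 37 (14 and 2.55).

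Where a gene was not well above background in a whole group, its change is given as a bound, or without a value where no bound can be had. The mean of the brighter side was set against the dimmer side, with each dim group at its floor, the lowest signal called well above background on its array. Gene lists were tested with camera at its preset correlation between genes of 0.01, then with the correlation estimated for each list, and with fry, which tests a list against no change. Adjustment was over all lists and comparisons. There were 31 lists, written from general knowledge. For each list member the limma result over all features was counted, and again after adjustment over the list alone. Camera called 146 of 434 tests on the 37 arrays, 31 of them with estimated correlation, and fry called 103. On the 48 arrays the counts were 135 of 465, 11 and 11.

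Genes were named by a rule that covers 6 kinds. These are the 4 targeted genes; the 12 highest and 12 lowest changes at 12 h and the 6 and 6 further ones at 24 h that went the same way in all wild-type lines and both replicates; for each dependence the 8 highest and 8 lowest at 12 h and 5 and 5 at 24 h with the same sign in both replicates; 6 and 6 for each untreated knockout; up to 4 members of each list; and 3 and 3 interval features at each time. Names that are only an accession, probe, clone or predicted locus were left out. Of the genes the rule gives, a part is described. Plotted genes and other genes outside the rule, such as Wars, the genes shared by 2 dependences, and Cdkn2a, Cdkn2b and Mtap, were chosen after their values were seen.

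Replicate numbers pair the samples, because wild-type and knockout arrays of a mediator with the same number and time were on the same run. The differences between replicates correlated at 0.339 to 0.572 between the 2 lines of a mediator, against a median of 0.186 over all pairs of groups. Run was confounded with treatment, since untreated and treated arrays were never on the same run. Runs were told apart by slide barcode and scan day in the files. The 6 runs carry only 3 slide barcodes, each in 2 runs. Bad spots shared by arrays with the same barcode and position numbered 47 in 24 pairs (0.549 expected by chance), against 203 in 96 pairs at the same position of another barcode (7.44 expected), so whether the same slides were used again stays open. Signal over background sets the depth of each array and is given with the first result. The correlation of ranks between replicates was 0.886 to 0.942 for the arrays outside runs 4 and 5.

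Fits were tested on simulated data with 200 changed features. For the 12 h wild-type response, 32.8% of changes of 2 log2 units were found on the 48 arrays and 93.7% on the 37. The 5 and 10 false calls need not hold for the real arrays, which share runs. The dependences on XBP1 and ATF6a at 12 h and ATF4 at 24 h had 0% on the 48 arrays. Counts of 0 there say little. On the 37 the shares were 17.9%, 4.92% and 17.9%.

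Alternatives tried were normexp background correction with an offset of 50 (on median spot signals, since mean signals are not in the files), quantile normalization, a median shift, the deposited table, no filter on dim probes (37119 features), only probes above background on all 48 arrays (774 features), the mean of all probes of a gene, a replicate block, a replicate block within each mediator, run as a random or fixed block, eBayes with trend and robust, only the arrays of the comparison, stricter thresholds and leaving out each array in turn. Sets of 40 arrays without the dim run and 46 without the 2 discordant libraries were added after seeing the data.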

Results

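Gene expression was measured on 48 arrays from 8 lines of mouse embryonic fibroblasts: a knockout line for each of XBP1, ATF4, ATF6a and ATF6b, and a wild-type line beside each. Each line had 3 groups of 2 arrays: untreated, 12 h and 24 h of tunicamycin. On 39 arrays, 46.1 to 60.2% of the 59305 non-control spots were well above background (27325 to 35689 spots). The 8 arrays of hybridisation run 4, which held the first experiment of the treated ATF6a and ATF6b lines, had 2.58 to 9.01% (1530 to 5345 spots). The second experiment of ATF6b wild type at 24 h had 35.6% (21098 spots), with 35.8% of its spots in local patches of lost or raised signal. Most counts of features are therefore given for the 48 arrays and for a set of 37 arrays without these 9 and without 2 libraries whose targeted genes went against their labels, while counts of list members and differences between dependences are from the 37 alone. Values of single genes are log2 changes ± SE from the 37 arrays, and their adjusted p values are from limma. Those of gene lists are from camera, with its preset correlation between genes and, where marked as estimated, with a correlation estimated for each list. A list call is one with an adjusted p under 0.05 at the preset correlation. The small number of arrays in each group limits the precision of all values.

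**Figure D1:**
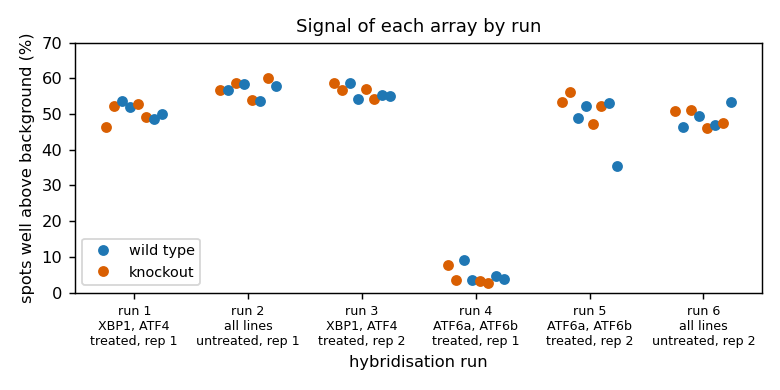
Share of spots well above background (percent, vertical axis) on each of the 48 arrays, by hybridisation run (horizontal axis), with each point an array of a wild-type or knockout line. The 8 arrays of run 4 sit between 2.58 and 9.01%, the partly failed array of run 5 at 35.6%, and the other arrays between 46.1 and 60.2%.

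The first comparison asked whether each knockout line had lost its targeted mRNA. Untreated ATF4 knockout cells had Atf4 values of 2.79 and -0.05 in the 2 experiments, against 7.22 and 7.20 in wild type (log2 signal relative to each array's 75th percentile). Untreated ATF6a knockout cells had Atf6 at -4.56 and -3.79, against 0.10 and -0.37. Untreated ATF6b knockout cells had Atf6b at -5.93 and -4.66, both not above background, against -0.04 and 0.46. The Xbp1 probe was not lower in untreated XBP1 knockout cells (5.09 and 4.67, against 5.02 and 4.61), so it does not tell the genotypes apart there and its place relative to the deletion is not given in the sources used here. After treatment it rose in wild type (6.14 to 6.52 in 4 libraries) and stood at 5.37 to 5.50 in 3 of the 4 libraries labelled XBP1 knockout. The other, the library labelled XBP1 knockout 24 h replicate 2, had Xbp1 at 6.36 and Atf4 at -2.84. The library labelled ATF4 knockout 24 h replicate 2 had Atf4 at 8.34 and Xbp1 at 5.37. These 2 libraries lay on the same run.

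Tunicamycin for 12 h was compared with no treatment over the 4 wild-type lines, to find the genes that respond to blocked N-glycosylation when all mediators are present. ER chaperones and folding enzymes rose: of 26 tested, 21 rose and 1 fell, with Sdf2l1 (4.81 ± 0.14), Hyou1 (3.88 ± 0.17), Creld2 (3.76 ± 0.13) and Pdia4 (3.41 ± 0.15) among those that rose most (adjusted p = 3.34e-20, estimated 0.00108). Genes of ER-associated degradation, which removes misfolded proteins, followed with 19 of 25 higher (20 adjusted over the list alone), led by Derl3 (at least 30.3-fold), Herpud1 (3.95 ± 0.21), Edem1 (2.39 ± 0.12) and Syvn1 (2.31 ± 0.10) (adjusted p = 4.12e-14, estimated 0.00181). Signal peptide recognition and translocation had 15 of 21 higher, among them Serp1 (1.77 ± 0.13) and Sec11c (1.71 ± 0.23) (adjusted p = 1.35e-07, estimated 0.0144). N-glycosylation and sugar-nucleotide supply had 20 higher and 2 lower of 36, with Alg12 (2.44 ± 0.16), Slc35b1 (2.25 ± 0.16) and Gnpnat1 (2.13 ± 0.15) (adjusted p = 1.14e-06, estimated 0.0238). The integrated stress response rose as well: 15 of 22 regulators were higher and 2 lower, with Ddit3 (4.50 ± 0.29), Atf3 (4.16 ± 0.33), Adm2 (4.74 ± 0.35) and Fgf21 (at least 22.1-fold) (adjusted p = 4.80e-09, estimated 0.0421). So did 20 of 24 genes of amino acid synthesis and transport, such as Slc6a9 (4.14 ± 0.27), Cth (3.34 ± 0.23), Slc3a2 (2.93 ± 0.22) and Slc7a11 (at least 27.1-fold) (adjusted p = 4.10e-15, estimated 0.0284). Of 19 cytosolic aminoacyl-tRNA synthetases 16 rose, such as Lars (1.98 ± 0.19) (adjusted p = 6.31e-10, estimated 0.139, where the call was lost). ER to Golgi transport had 13 higher and 2 lower of 31, Bet1 (1.55 ± 0.21) among them (adjusted p = 0.0179, estimated 0.471, where the call was also lost).

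The same 12 h of tunicamycin lowered the matrix and contractile genes of the wild-type fibroblasts. Of 22 extracellular matrix and fibroblast markers 20 fell, such as Dcn (-3.75 ± 0.72), Thy1 (-3.57 ± 0.37) and Thbs2 (at least 8.37-fold). Of 12 myofibroblast and smooth muscle markers 11 fell, such as Cnn1 (-3.38 ± 0.26), Myl9 (-3.33 ± 0.31), Tagln (-2.67 ± 0.21) and Actg2 (-3.40 ± 0.31). Neither list kept its call with an estimated correlation (adjusted p = 0.113 and 0.0662, from 3.78e-12 and 8.23e-12 with the preset one). Other genes that fell were Il6 (at least 44.1-fold), Cxcl1 (at least 25.0-fold), Saa3 (at least 103-fold), Hp (at least 57.7-fold) and Mmp3 (at least 33.9-fold), and 14 of 19 NF-kB and chemokine genes were lower (estimated adjusted p = 0.388). Interferon-stimulated genes had 9 of 20 lower (Psmb8 (at least 12.4-fold); estimated adjusted p = 0.617) and cholesterol synthesis 11 lower and 1 higher of 22 (Hsd17b7 (-2.80 ± 0.26); estimated adjusted p = 0.568). Of 8 candidate substrates of regulated IRE1-dependent decay, 4 fell, among them Scara3 (-2.79 ± 0.28), Col6a1 (-1.90 ± 0.35) and Bloc1s1 (-1.20 ± 0.20) (estimated adjusted p = 0.282). Of 14 named long noncoding RNAs, 5 rose, among them Snhg12 (2.04 ± 0.22), Snhg1 (1.94 ± 0.16) and Mir17hg (1.40 ± 0.25), and 2 fell, among them H19 (-3.71 ± 0.65). Of 18 NRF2 antioxidant genes 6 rose, such as Hmox1 (1.97 ± 0.17), and of 29 cell cycle genes 1 fell, with camera calling neither list.

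**Figure D2:**
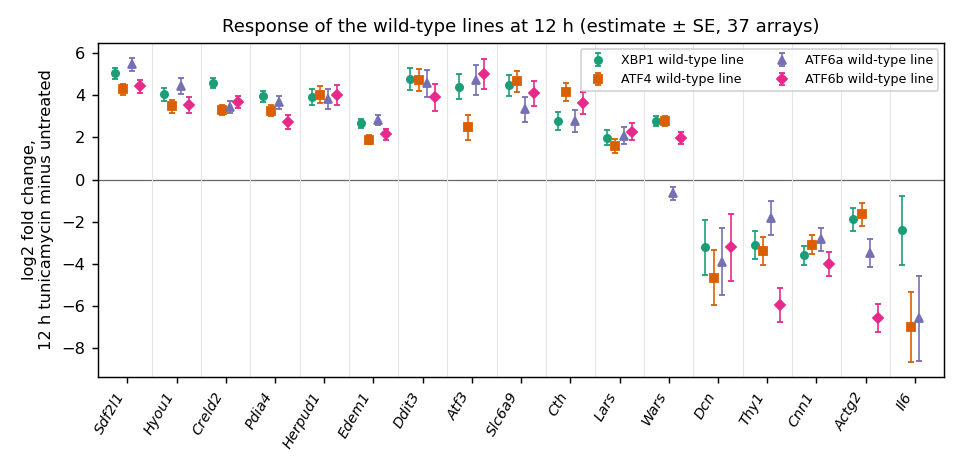
Log2 change at 12 h of tunicamycin minus untreated (vertical axis) for 17 genes (horizontal axis) in each of the 4 wild-type lines, from the 37 arrays, with error bars of 1 SE. Chaperone, degradation and stress-response genes lie above 0 and matrix, contractile and cytokine genes below it, on the scale of the 75th percentile. Wars is below 0 in the ATF6a line, and Il6 has no point for the ATF6b line, where 1 side was not well above background.

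Other genes with large rises at 12 h were Car6 (at least 276-fold), Acox2 (at least 23.1-fold), B4galnt2 (at least 23.5-fold), Soat2 (5.44 ± 0.33) and Angptl6 (5.42 ± 0.31). Large falls were also seen for Slpi (at least 18.1-fold), Sfrp1 (at least 14.9-fold), Serping1 (at least 19.3-fold) and Saa1 (-4.74 ± 1.03). On the 37 arrays 7740 of 22796 features passed, 4505 higher and 3235 lower, and on the 48 arrays 2024 of 25143, 1418 higher and 606 lower. Leaving out 1 array at a time gave 955 to 2938 on the 48. The share that rose depended on the scale: with quantile normalization the 48 arrays gave 140 higher and 356 lower. Relative to each array's median every 12 h value was lower by 0.25 and 2073 features were higher and 4431 lower on the 37 arrays, and normexp correction gave 5631 and 2472. On the median scale 19 ER chaperones and folding enzymes still rose, 4 genes of ER to Golgi transport rose and 3 fell. No run held both untreated and treated arrays, so run was confounded with treatment and could enter only as a random block, which left 5473 features on the 37 arrays and 0 on the 48 (limma, 5410 at an unadjusted p under 0.05 without the block).

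At 24 h the question was the same, with 4 wild-type lines on the 48 arrays and 3 on the 37, where ATF6b wild type had no usable array. The chaperones stayed above untreated cells, with 23 of 28 higher and 1 lower, led by Sdf2l1 (4.68 ± 0.16) (adjusted p = 2.31e-22, estimated 0.000841). Of the degradation genes 17 of 25 rose (estimated adjusted p = 0.00169), of signal peptide recognition and translocation 17 of 23 (estimated adjusted p = 0.00706), and of N-glycosylation and sugar-nucleotide supply 19 of 39 (24 higher and 2 lower adjusted over the list alone; estimated adjusted p = 0.0146). The integrated stress response had 20 of 26 higher (estimated adjusted p = 0.0237), amino acid synthesis and transport 22 of 26 (estimated adjusted p = 0.0329), and aminoacyl-tRNA synthetases 16 of 21 (estimated adjusted p = 0.113). ER to Golgi transport had 16 higher and 1 lower of 36 (estimated adjusted p = 0.388), but its median of 0.25 became -0.05 on the median scale, with 3 higher and 1 lower. The glutathione transferases Gsta1 (at least 37.7-fold) and Gsta2 (at least 11.1-fold) had large rises, with Avil (at least 26.5-fold) and Cyb5r2 (at least 14.9-fold). Large falls were those of Fst (-5.04 ± 0.30), Clu (-5.09 ± 0.75), Srpx (at least 21.6-fold), Lum (at least 8.44-fold) and Il33 (at least 11.6-fold). Of 26 matrix markers 22 fell (estimated adjusted p = 0.0662), of 12 contractile markers 10 (estimated adjusted p = 0.0678), of 21 NF-kB and chemokine genes 15 (estimated adjusted p = 0.264), and of 24 cholesterol synthesis genes 14 (estimated adjusted p = 0.527). Counts were 6186 of 24426 features on the 37 arrays, 3576 higher and 2610 lower, and 2883 of 25154 on the 48, 1959 higher and 924 lower. Relative to the array median, every 24 h value was lower by 0.30, with 1428 higher and 3608 lower on the 37 arrays, and the deposited value table gave 2995 and 3301. Without 1 array at a time the 48 gave 1423 to 5405, and with quantile normalization 178 higher and 485 lower. A random run block left 4600 features on the 37 arrays and 0 on the 48 (limma, 7221 at an unadjusted p under 0.05 without the block).

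Comparing 24 h with 12 h asked which genes kept moving during treatment, within the same runs. On the 37 arrays 30 of 22568 features passed, 14 higher and 16 lower at 24 h, and on the 48 arrays limma called 0 of 25157, with 458 at an unadjusted p under 0.05. Leaving out ATF6b wild type 24 h replicate 1 decides nothing, since only the partly failed array is left. With run as a fixed block 96 features passed on the 37 arrays, and 14 of 16 divisions within runs (chosen after seeing the result) gave at least 96, so chance cannot be excluded for these features. The aminoacyl-tRNA synthetase Wars was higher at 24 h (0.94 ± 0.16, adjusted p = 0.0181). Extracellular matrix and fibroblast markers moved down further as a list (adjusted p = 0.000189, estimated 0.464), with 0 single members past the limit, and so did myofibroblast and smooth muscle markers (adjusted p = 0.0150, estimated 0.571). Without the mask of local patches 491 features passed, since patches lay on some of these arrays.

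Probes named by a genomic interval were taken as long intergenic noncoding RNA features, since the files name no such class. They were not matched to genes, so some may be coding. Features with large rises at 12 h included 3 neighbouring ones on the same stretch of mouse chromosome 5, at 15146475 to 15170100 (build mm9; at least 31.7-fold), 15033568 to 15033987 (at least 27.7-fold) and 14943275 to 14944205 (at least 32.7-fold). Features with large falls lay on chromosome 10 at 83185606 to 83225506 (at least 16.7-fold lower), on chromosome 7 at 91558475 to 91733625 (-4.18 ± 0.38) and on chromosome 1 at 138579972 to 138587381 (at least 9.17-fold lower). At 24 h, overlapping features on chromosome 9 at 78107225 to 78118850 and 78104935 to 78116974 also had large rises (at least 30.6-fold and 4.58 ± 0.66). At 12 h 777 of 3046 interval features passed on the 37 arrays, 499 higher and 278 lower, and 285 on the 48, 266 higher and 19 lower. At 24 h the counts were 524 (367 higher, 157 lower) and 412 (375 higher, 37 lower). On the 48, leaving out 1 array at a time gave 125 to 504 at 12 h and 183 to 855 at 24 h, and quantile normalization 26 and 35. Leaving out XBP1 wild type 24 h replicate 2 or ATF4 wild type 24 h replicate 2 brought the 24 h count on the 37 arrays to 308 or 332. In the 12 h dependences described next, 2 interval features passed for XBP1, 61 for ATF4, 3 for ATF6a and 13 for ATF6b on the 37 arrays.

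The dependence of the response on a mediator was measured as the response of its knockout line minus that of its wild-type line, so a negative value marks a smaller rise or a larger fall without the mediator. Without XBP1, the chaperone response was reduced. Creld2 rose by 4.61 ± 0.24 in wild type and by 1.15 ± 0.24 in the knockout at 12 h, a difference of -3.45 ± 0.33, adjusted p = 0.000295. Edem1, which takes misfolded glycoproteins to degradation, rose by 2.68 ± 0.21 in wild type and its change in the knockout (0.20 ± 0.21) did not pass, a difference of -2.48 ± 0.30. Of 28 ER chaperones and folding enzymes 8 depended on XBP1 at 12 h (17 adjusted over the list alone), Sdf2l1 (-2.81 ± 0.35), Dnajb9 (-2.49 ± 0.48) and Hyou1 (-2.20 ± 0.43) among them (adjusted p = 3.72e-30, estimated 0.000430). Single members of related lists did too: Syvn1 (-1.59 ± 0.24) in degradation (2 of 26; estimated adjusted p = 0.00181), Serp1 (-1.74 ± 0.34) in translocation (1 of 24; estimated adjusted p = 0.00253) and Alg12 (-2.06 ± 0.41) in N-glycosylation (1 of 41; estimated adjusted p = 0.0371). ER to Golgi transport was lower as a list with 0 members past the limit (estimated adjusted p = 0.0198). Amino acid genes had 0 of 27 past the limit, and that list's preset call was lost (estimated adjusted p = 0.104). Other genes lower without XBP1 were Rab38 (-4.41 ± 0.61) and Etv1 (-3.63 ± 0.63), and Tceal3 (at least 57.1-fold), Tceal6 (5.92 ± 0.72), Pogk (3.45 ± 0.57) and Mboat2 (3.41 ± 0.62) were higher.

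At 24 h the XBP1 dependence had 4 of 28 ER chaperones and folding enzymes lower (16 adjusted over the list alone), with Creld2 (-3.31 ± 0.37), Sdf2l1 (-2.42 ± 0.39) and Dnajc3 (-1.97 ± 0.31) (adjusted p = 9.67e-27, estimated 0.000451). The same held for Edem1 (-2.37 ± 0.33), Hid1 (-3.93 ± 0.56), Ero1b (-2.56 ± 0.44) and Mitf (-2.87 ± 0.49), while Plcl2 (2.54 ± 0.43) was higher. The signal peptide recognition and translocation list kept its call (estimated adjusted p = 0.00602) with 0 single members past the limit. Counts on the 37 arrays were 67 of 25142 at 12 h (26 higher, 41 lower) and 19 of 25150 at 24 h (5 higher, 14 lower). With quantile normalization they were 48 higher and 49 lower, and 28 and 23. On the median scale they were 3 and 9, and 1 and 1. On the 48 arrays limma called 0 at both times, with 77 and 147 at an unadjusted p under 0.05. A fixed block for run, which these contrasts within runs allow, gave 141 and 48 on the 37 arrays and 3 and 1 on the 48. The knockout at 24 h was a single array, assumed to vary like the other groups. Leaving out XBP1 wild type 12 h replicate 1 brought the 12 h count to 16, and leaving out untreated XBP1 wild type replicate 1 brought the 24 h count to 1.

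In the ATF4 knockout line, many amino acid genes rose less or not at all. Cth, the enzyme that makes cysteine from cystathionine, rose by 4.16 ± 0.42 in wild type at 12 h and fell by 1.86 ± 0.42 in the knockout, a difference of -6.02 ± 0.59, adjusted p = 0.000224. Chac1, a glutathione-degrading enzyme, rose by 4.76 ± 0.49 in wild type and its change in the knockout (-0.58 ± 0.49) did not pass, a difference of -5.33 ± 0.69, adjusted p = 0.000959. Of 27 genes of amino acid synthesis and transport 15 depended on ATF4 at 12 h (21 adjusted over the list alone), among them Psat1 (-4.06 ± 0.58), Aldh1l2 (-4.06 ± 1.13) and Slc6a9 (-3.97 ± 0.68) (adjusted p = 1.63e-14, estimated 0.0324). Cytosolic aminoacyl-tRNA synthetases had 13 of 21 lower (17 over the list alone), such as Lars (-2.51 ± 0.48) and Gars (-2.33 ± 0.38) (adjusted p = 2.02e-14, estimated 0.0662). Integrated stress response regulators had 7 of 26 lower (14 over the list alone), such as Stc2 (-5.12 ± 0.81) and Adm2 (at least 6.20-fold) (adjusted p = 4.96e-07, estimated 0.0783). Cholesterol synthesis had 13 of 24 lower (estimated adjusted p = 0.360). Chaperones had 1 of 28 lower, and their median of -0.21 became 0.30 with quantile normalization for the list ER chaperones and folding enzymes.

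Other genes were higher in the ATF4 knockout response at 12 h, Lum (at least 68.2-fold), Gbp4 (at least 39.1-fold), Uba7 (7.83 ± 1.83), C3 (10.49 ± 2.56) and Cfb (at least 722-fold) among them. The 12 h estimates for C3 were -5.88 ± 1.81 in wild type and 4.60 ± 1.81 in the knockout, neither of which passed alone. Of 22 interferon-stimulated genes 3 were higher (11 adjusted over the list alone; estimated adjusted p = 0.464). Negative values included Cox6a2 (-7.29 ± 1.22) and Tmem47 (at least 19.1-fold), and Tmem47 was the 1 feature that limma called on the 48 arrays (529 at an unadjusted p under 0.05). At 24 h 10 of 27 amino acid genes depended on ATF4 (adjusted p = 1.73e-15, estimated 0.0267), with Cth (-5.80 ± 0.66) and Asns (-3.41 ± 0.57). So did 5 of 26 stress regulators (estimated adjusted p = 0.0464) and 6 of 21 tRNA synthetases (estimated adjusted p = 0.0733), while Enpp2 (6.87 ± 1.28) and Mgst2 (5.83 ± 1.18) were higher. Counts on the 37 arrays were 1385 of 25169 at 12 h (592 higher, 793 lower) and 266 of 25169 at 24 h (159 of them lower). Quantile normalization turned these splits to 563 higher and 469 lower, and 127 and 121, and the median scale that at 24 h to 51 and 45. On the 48 arrays limma called 0 at 24 h, with 361 at an unadjusted p under 0.05. The fixed run block gave 2864 and 693 on the 37 arrays and 315 and 91 on the 48. Leaving out untreated ATF4 knockout replicate 2 brought the counts to 305 and 34, and leaving out replicate 1 to 1778 and 585. The knockout at 24 h was 1 array.

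In ATF6a knockout cells, too, part of the chaperone response was reduced. Sdf2l1 rose by 5.47 ± 0.30 in wild type and by 1.88 ± 0.30 in the knockout at 12 h, a difference of -3.59 ± 0.43, adjusted p = 0.000485. At 24 h Creld2 rose by 3.88 ± 0.29 in wild type, its change in the knockout (0.29 ± 0.29) did not pass, and the difference was -3.59 ± 0.41, adjusted p = 0.000401. Of 26 ER chaperones and folding enzymes 4 depended on ATF6a at 12 h (10 adjusted over the list alone; adjusted p = 3.29e-16, estimated 0.00181), with Creld2 (-2.82 ± 0.41) and Pdia4 (-2.79 ± 0.46). At 24 h 6 of 28 did (13 over the list alone; adjusted p = 1.25e-19, estimated 0.00108), with Sdf2l1 (-3.20 ± 0.43), Pdia4 (-2.88 ± 0.46) and Dnajc3 (-2.65 ± 0.34). Degradation genes had 2 of 25 lower at 12 h, Syvn1 (-2.08 ± 0.30) and Edem1 (-1.81 ± 0.37) (estimated adjusted p = 0.0239), and 1 of 25 at 24 h (estimated adjusted p = 0.0405). Of genes of mesothelium and early endoderm, high in untreated ATF6a wild-type cells, Crb2 had a positive value at 12 h (at least 72.5-fold). For Foxa2, Lrrn4, Upk1b and Upk3b no value can be given, since they were not well above background in the knockout before or after treatment, and they fell in wild type (at least 90.9-, 38.3-, 169- and 102-fold). Hoxd13 (at least 6.01-fold) and Hoxa11 (-3.78 ± 0.52) were lower. Mbp (7.48 ± 0.77) and the Y-linked Ddx3y (at least 3.57-fold) were higher at 12 h and Bmp4 (7.11 ± 0.95) and Slc1a6 (7.68 ± 1.28) at 24 h. Crybb3 (at least 1453-fold) and Tmem253 (-8.84) had large negative values at 12 h, each from 1 bright spot on the single wild-type array, and the deposited value table gave 0.1 and 0.6 for them. Counts on the 37 arrays were 98 of 22886 at 12 h (67 higher, 31 lower) and 131 of 24009 at 24 h (77 higher, 54 lower). Normexp correction made the 12 h split 42 and 50, and the median scale made it 28 and 18, with 45 and 20 at 24 h. On the 48 arrays limma called 0 at both times, with 91 and 72 at an unadjusted p under 0.05. The fixed run block gave 233 and 240 on the 37 arrays and 22 and 17 on the 48. Each treated group was 1 array here, assumed to vary like the other groups, and leaving out untreated ATF6a wild type replicate 1 brought the counts to 64 and 87.

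Without ATF6b, no difference in the chaperone response was seen at 12 h: limma called 0 of 28 (with 2488 of all features at an unadjusted p under 0.05), and camera gave that list an adjusted p of 0.460. Contractile genes were higher in the knockout's response, with 3 of 12 myofibroblast and smooth muscle markers past the limit (8 higher and 1 lower adjusted over the list alone), Actg2 (6.12 ± 0.95) among them (adjusted p = 1.30e-05, estimated 0.289). Hox genes had 4 of 37 higher (adjusted p = 7.97e-07, estimated 0.147). Each side of these values rests on a single treated array, and since Mtap, Cdkn2a and Cdkn2b were also low on that of the wild type, they cannot be told apart from a change of that culture. Loxl2 (8.32 ± 1.09), a collagen cross-linking enzyme, and the cell cycle inhibitor Cdkn2b (at least 41.8-fold) were higher, and Cdsn (-5.54 ± 1.00), Vegfd (-4.28 ± 0.58), Crabp1 (-4.95 ± 0.88), Cd34 (-4.84 ± 0.91) and Bmp4 (-4.83 ± 0.95) were lower. Cdkn2b was not well above background on the treated wild-type array, at least 68.9- and 267-fold below untreated cells by its 2 probes. On the treated knockout array these probes stood at 0.746 and 2.38, also below the untreated knockout (2.72 and 3.39, and 4.81 and 5.26). Counts on the 37 arrays were 152 of 23439 at 12 h, 100 higher and 52 lower, and on the 48 arrays limma called 0 at 12 h and 0 at 24 h, with 134 and 1169 at an unadjusted p under 0.05. With run as a fixed block there were 564 at 12 h on the 37 arrays, and 0 at 12 h and 41 at 24 h on the 48. Leaving out ATF6b wild type 24 h replicate 1 left only the partly failed array there, so that fit decides nothing. The 37 arrays had no 24 h contrast. Both treated groups were single arrays, and leaving out untreated ATF6b knockout replicate 2 brought the count to 84.

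The dependences on XBP1 and on ATF6a met in a small group of ER genes. Lower without either mediator at 12 h were 6 features, Creld2, Edem1, Ero1b, Pdia4, Sdf2l1 and Syvn1, where 0.0515 were expected by chance (Fisher's exact test across genes, two-sided p = 9.91e-12). At 24 h there were 3, Creld2, Dnajc3 and Sdf2l1, with 0.0292 expected (Fisher's exact p = 3.03e-06). XBP1 and ATF4 shared 3 at 12 h, Hid1, Serp1 and Tmem179, with 1.29 expected (Fisher's exact p = 0.139). Genes are not independent replicates, so these p values hold only across genes, and 9 such overlaps were computed. Over all features the 9 correlations of dependence between mediators were low, with Pearson's r from -0.0382 to 0.183 across genes.

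**Figure D3:**
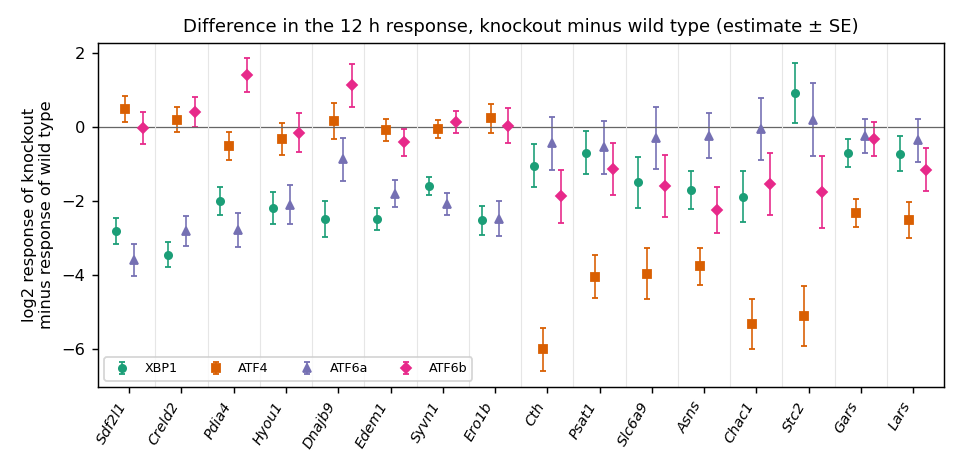
Response of the knockout line minus that of the wild-type line at 12 h (log2, vertical axis) for 16 genes (horizontal axis), with a point for each mediator and error bars of 1 SE, from the 37 arrays. Sdf2l1, Creld2, Edem1 and Syvn1 lie below 0 for XBP1 and ATF6a, and Cth, Psat1, Chac1 and Stc2 lie lowest for ATF4.

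Untreated knockout and wild-type lines were also compared, with a single line of each genotype per mediator, so line and genotype cannot be told apart. Untreated XBP1 knockout cells had p53 targets raised, with 8 of 21 higher and 1 lower, Cdkn1a (6.90 ± 0.73), Eda2r (at least 2.24-fold) and Zmat3 (2.78 ± 0.34) among the former and Perp (-3.79 ± 0.70) the latter (adjusted p = 4.62e-07, estimated 0.113). Of 26 integrated stress response regulators 6 were higher, such as Trib3 (3.30 ± 0.65) and Chac1 (2.14 ± 0.49) (adjusted p = 9.39e-05, estimated 0.178). Position genes differed widely: of 37 Hox genes 13 were higher and 8 lower, with Hoxd10 (at least 116-fold) and Hoxa10 (at least 83.7-fold) higher, as were Tbx5 (at least 123-fold) and Pcbd1 (at least 839.8-fold), and Tbx1 (at least 166-fold) was lower. Of 5 sex-linked genes 3 were lower, Eif2s3y (at least 88.9-fold) and Ddx3y (at least 40.2-fold) among them, and Xist (at least 32.0-fold) was higher (adjusted p = 1.42e-05, estimated 0.0991). Of ER chaperones and folding enzymes 4 of 28 were lower, with a median of -0.07 that became 0.13 on the median scale. In all, 1221 of 25153 features differed on the 37 arrays, 589 higher and 632 lower, and 51 on the 48, 21 higher and 30 lower. The 2 replicates of a line shared its run with the other line, and the fixed run block gave 1974 on the 37 arrays and 570 on the 48. Leaving out untreated XBP1 wild type replicate 1 or 2 brought the count on the 37 arrays to 641 or 781, and leaving out any 1 of the 4 arrays gave 6 to 12 on the 48.

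Among the genes lower in untreated ATF4 knockout than wild-type cells were Lcn2 (-8.38 ± 2.14), Saa1 (-7.55 ± 1.85), Gda (-7.37 ± 0.90), Trim30a (-7.25 ± 1.78) and Oas3 (at least 82.4-fold). Of 26 integrated stress response regulators 6 were lower, Adm2 (-3.17 ± 0.62), Trib3 (-2.87 ± 0.65) and Vegfa (-2.68 ± 0.40) among them (adjusted p = 2.15e-07, estimated 0.0678). Of 24 glycolysis and hypoxia genes 6 were lower and 1 higher (estimated adjusted p = 0.139). The myosins Myh1 (at least 38.3-fold) and Myh8 (at least 41.6-fold) were higher. So were 4 of 17 named long noncoding RNAs (Dnm3os (2.33 ± 0.45), adjusted p = 0.000119, estimated 0.0238) and 14 Hox genes, with 4 lower. Tmem41b was higher (6.37 ± 0.85), but the probe above background on all arrays gave -0.39. In all, 1387 of 25169 features differed on the 37 arrays, 492 higher and 895 lower, and 14 on the 48, 2 higher and 12 lower, and the fixed run block gave 2129 on the 37 arrays and 671 on the 48. Without untreated ATF4 wild type replicate 1 or 2 the count on the 37 arrays was 618 or 894, without untreated ATF4 knockout replicate 1 or 2 it was 924 or 737, and on the 48 it was 0 or 1.

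Genes far lower in untreated ATF6a knockout than wild-type cells included Wt1 (-8.50 ± 0.79), Upk1b (at least 175-fold), Foxa2 (at least 96.0-fold) and Ddx4 (at least 135-fold), with the Y-linked Eif2s3y (at least 199-fold) and Ddx3y (at least 129.9-fold) also lower and Xist (at least 55.8-fold) higher (adjusted p = 5.86e-11, estimated 0.0166 for sex-linked genes, 4 of 5 lower and 1 higher). Ifi202b (8.55 ± 1.37), Ucp2 (6.61 ± 0.73) and Cxcl14 (6.02 ± 1.14) were higher. Of 37 Hox genes 5 were lower and 1 higher. In all, 339 of 25169 features differed on the 37 arrays, 124 higher and 215 lower, and 4 on the 48, 1 higher and 3 lower. Untreated ATF6b knockout cells expressed Srpx (at least 78.2-fold), Ptgis (6.24 ± 0.55), Igfbp2 (5.88 ± 1.16) and Vip (5.76 ± 1.20) more than wild type. They expressed Igf2 (at least 72.2-fold), Arhgap36 (at least 111-fold), Hoxc6 (-7.57 ± 0.73) and Hoxc9 (at least 48.4-fold) less, with 10 of 37 Hox genes lower and 1 higher. Of 27 amino acid genes 6 were higher, with Slc7a3 (4.81 ± 0.60) and Cth (2.78 ± 0.42) (adjusted p = 7.70e-11, estimated 0.0678), and of 26 integrated stress response regulators 6 (adjusted p = 2.03e-07, estimated 0.0678). In all, 717 of 25167 features differed on the 37 arrays, 351 higher and 366 lower, and 14 on the 48, 1 higher and 13 lower. The fixed run block gave 547 for ATF6a and 1341 for ATF6b on the 37 arrays, and 139 and 269 on the 48, and leaving out untreated ATF6a wild type replicate 1 brought the 339 for ATF6a to 195. Leaving out untreated ATF6b wild type replicate 2 brought the 717 for ATF6b to 233, and leaving out untreated ATF6b knockout replicate 1 or 2 to 312 or 264. Leaving out 1 of its 4 untreated arrays lowered each count on the 48.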

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

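The tests of exchanged libraries, of left-over signal and of a lost locus, and the differences between dependences, were chosen only after the result was seen. The test of differences among lines was planned for the 48 arrays.

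The dependences on 2 mediators differed in a small part of the features, ER genes and amino acid genes among them. Of these, Creld2 (-3.66 ± 0.47), Sdf2l1 (-3.31 ± 0.50), Alg12 (-3.05 ± 0.57) and Edem1 (-2.40 ± 0.42) were lower in the XBP1 than in the ATF4 dependence at 12 h, while Cth (4.98 ± 0.84) and Stc2 (6.04 ± 1.14) were higher there. At 12 h, 52 features differed between XBP1 and ATF4, 34 between XBP1 and ATF6a, 91 between XBP1 and ATF6b, 108 between ATF4 and ATF6a, 312 between ATF4 and ATF6b, and 56 between ATF6a and ATF6b, by the difference of the 2 interactions on the 37 arrays. At 24 h, where ATF6b could not be compared, 18 differed between XBP1 and ATF4, 16 between XBP1 and ATF6a, and 33 between ATF4 and ATF6a. At 12 h, Sdf2l1 (4.09 ± 0.56) was higher in the ATF4 than in the ATF6a dependence, and Sdf2l1 (-2.78 ± 0.56) was lower in the XBP1 than in the ATF6b dependence. Overlap of these contrasts with the line differences described next was not counted.

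The wild-type lines responded differently in 1199 features of the 37 arrays by the moderated F test. On the 48 limma called 0 (1174 at an unadjusted p under 0.05). Lrrn4, Upk3b and Foxa2 were among the features with the lowest p, and fell at 12 h in ATF6a wild type (at least 38.3-, 102- and 90.9-fold). Lrrn4 and Upk3b were not well above background in the other 3 lines, and Foxa2 also fell in the XBP1 line (at least 3.24-fold). Cdkn2b, Cdkn2a and Mtap fell in ATF6b wild type (at least 266-fold, -7.92 ± 0.52 and at least 38.7-fold) and lay between -0.52 and 0.41 in the XBP1 and ATF4 lines and between -1.41 (Mtap) and -0.11 in the ATF6a line. Leaving out ATF4 wild type untreated replicate 2, ATF6a wild type untreated replicate 1 or XBP1 wild type untreated replicate 1 gave 681, 787 or 777 features. Cavin2, Dynlt3, Ppp1cc and Tubb4a, also with low p, rest on the single treated arrays of the ATF6a line, where small patches of changed signal may remain, since 2203 features passed without the mask of local patches.

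A spike-in control of E1A sequence, which no comparison used, stood out in run 3, with a median of 14.3 (log2 signal), 5.36 above the untreated runs at 8.75 and 9.19. Its medians in the other treated runs were 10.1, 5.68 and 11.8 for runs 1, 4 and 5. Why its signal differed between runs was not tested.

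The first pattern is that the libraries labelled XBP1 knockout 24 h replicate 2 and ATF4 knockout 24 h replicate 2 carry targeted genes against their labels. Signal left from an earlier hybridisation on the same slide position could only add to Atf4, yet in the former Atf4 lay at -11.52 relative to the other treated XBP1 knockout libraries, which argues against it. An exchange of the 2 libraries is a candidate explanation: over all features other than the targeted genes, each followed the other line, and the lower of the 2 correlations with the other line's side was 0.61. That test could have come out near 0, but it was set after the targeted genes were seen, and an exchange at any step from culture to file would look the same. Both libraries are left out of the 37 arrays.

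The second pattern is the joint fall of Mtap, Cdkn2a and Cdkn2b in treated ATF6b wild-type cells. A response to tunicamycin in every line is argued against by a median change of -0.090 at 12 h in the other wild-type lines, and weak signal by the 0.0533% of 9376 equally bright probes that fell as far on the same array (0.309% with dim spots set to the lowest signal called well above background). The 3 genes are neighbours on the genome, and of 27 measured genes among the 20 nearest on either side, 0 fell by over 4 log2 units, which goes with a loss of the locus from the treated culture. The bright Cdkn2a probe changed by -7.86 on the single 12 h array and by -5.63 on the partly failed 24 h array. The other 4 of the 5 probes were not well above background on either, at least 38.8- to 267-fold and at least 5.28- to 36.3-fold lower than untreated. Loss of the locus, or treated cultures of another origin, may therefore underlie these values, and no DNA was measured.

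The third pattern is the high level of mesothelial and endoderm genes (Upk1b, Upk3b, Wt1, Msln, Lrrn4, Gpm6a, Foxa2 and Crb2) in untreated ATF6a wild-type cells. Whether tunicamycin lowers these genes in every line stays open: the 6 values that could be measured in the other lines, of 3 genes, went both ways at 12 h, with 4 higher and 2 lower (Wt1 at least 11.8-fold and Foxa2 at least 3.24-fold lower in the XBP1 line, Msln at 1.44, 4.11 and 1.78 and Foxa2 at 1.46 in the ATF4 line), so their median of 1.45 decides nothing. Cells of mesothelial type in the untreated culture are a candidate. Of 6 other mesothelial genes, listed before the test, 5 were higher there by over 1 and Nkain4 was not (-0.046). Their median was 2.27 (2.19 with dim spots set as above). Fibroblast cultures can express several of these keratins, and the sources give no sort of cells. Another origin of the treated than of the untreated culture stays open and was not tested, so the ATF6a dependence of these genes cannot be read as an effect of ATF6a.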

How the results depend on the processing

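The alternatives of the 48-array analysis were chosen before the data were examined, and the 37-array analysis with all its alternatives, the 40 arrays and the 46 arrays were chosen after seeing the data. Signal over background limited the 48 arrays: 8 of them measured at most 9.01% of their spots, and the median residual SD was 1.26, against 0.454 on the 37 arrays. On 40 arrays, as without ATF6b wild type 24 h replicate 1, the partly failed array stood alone for its group. Over the settings of the 37 arrays, the wild-type response held 3861 to 9123 features at 12 h and 3252 to 7256 at 24 h, while most dependences moved by more than 1.5 times under several. The planned slide block was taken as hybridisation run, and as a fixed block it could not be fitted for tunicamycin against untreated. The limit of at least 2-fold moved no count of the 48 arrays by more than 1.5 times. Where fewer features, fewer arrays or a stricter limit are not named as the reason, the cause was not tested.

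The following are counts of the 48 arrays that moved by more than 1.5 times or away from 0. An adjusted p under 0.01 gave 723 and 1043 in wild type at 12 h and 24 h, 104 and 146 interval features, 20, 1, 1 and 1 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, and 0 in the 12 h dependence on ATF4. Normexp correction with the 75th percentile gave 33, 22 and 25 in untreated knockouts of ATF4, ATF6a and ATF6b, 0 and 2 in 12 h dependences on ATF4 and ATF6a, 156 for knockout against wild type after treatment, and 1 for differences among wild-type lines. Quantile normalization gave 496 and 663 in wild type at 12 h and 24 h, 26 and 35 interval features, 3 for 24 h against 12 h, 30, 13 and 3 in untreated knockouts of XBP1, ATF6a and ATF6b, 4, 2 and 5 in 12 h dependences on ATF4, ATF6a and ATF6b, 3 and 7 in 24 h dependences on ATF6a and ATF6b, 1504 over the responses of single lines, 892 for knockout against wild type after treatment, and 22 for differences among wild-type lines. The median shift gave 260 interval features at 24 h, 82, 72, 37 and 7 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 5 and 2 in 12 h dependences on ATF4 and ATF6a, 1 and 2 in 24 h dependences on ATF4 and ATF6a, and 1 for differences among wild-type lines. With the deposited value table there were 6885 and 6807 in wild type at 12 h and 24 h, 467 interval features at 12 h, 3 for 24 h against 12 h, 935, 924, 250 and 613 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 59, 632, 72 and 286 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, 80, 274, 89 and 201 in 24 h dependences on XBP1, ATF4, ATF6a and ATF6b, 26653 over the responses of single lines, 12644 for knockout against wild type after treatment, and 1093 for differences among wild-type lines. Without a filter on dim probes, which tests more features, there were 3, 1 and 4 in untreated knockouts of ATF4, ATF6a and ATF6b, and 0 in the 12 h dependence on ATF4. With only probes above background on all arrays, a set of 774 features, there were 4 and 4 in wild type at 12 h and 24 h, 0 and 0 interval features, 0, 0, 0 and 0 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, and 0 in the 12 h dependence on ATF4. The mean of all tested probes gave 2 in the untreated knockout of ATF6a, and 2 for differences among wild-type lines. With trend and robust in eBayes there were 30 and 24 in untreated knockouts of ATF4 and ATF6b, 0 in the 12 h dependence on ATF4, and 2 for differences among wild-type lines. The replicate block gave 3076 and 4659 in wild type at 12 h and 24 h, 454 and 741 interval features, 32 in the untreated knockout of ATF4, 3 in the 12 h dependence on ATF4, and 428 for knockout against wild type after treatment. The replicate block within mediator gave 5983 and 8475 in wild type at 12 h and 24 h, 1055 and 1466 interval features, 134, 144, 17 and 41 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 34 in the 12 h dependence on ATF4, and 16 for differences among wild-type lines. Run as a fixed block gave 570, 671, 139 and 269 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 3, 315 and 22 in 12 h dependences on XBP1, ATF4 and ATF6a, 1, 91, 17 and 41 in 24 h dependences on XBP1, ATF4, ATF6a and ATF6b, and 6532 for knockout against wild type after treatment. Run as a random block, with a consensus correlation of 0.733, gave 0 and 0 in wild type at 12 h and 24 h, 0 and 0 interval features, 547, 677, 143 and 264 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 287 and 22 in 12 h dependences on ATF4 and ATF6a, 77, 14 and 7 in 24 h dependences on ATF4, ATF6a and ATF6b, 353 over the responses of single lines, 6534 for knockout against wild type after treatment, and 57 for differences among wild-type lines. Fits to only the arrays of the comparison, with fewer samples, gave 466, 328, 0 and 0 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, and 37 in the 12 h dependence on ATF4. Without the 8 arrays of the dim run (40 arrays) there were 7865 and 11279 in wild type at 12 h and 24 h, 797 and 1153 interval features, 4225 for 24 h against 12 h, 767, 777, 210 and 415 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 11, 353, 239 and 162 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, 14, 93, 146 and 7555 in 24 h dependences on XBP1, ATF4, ATF6a and ATF6b, 31787 over the responses of single lines, 18726 for knockout against wild type after treatment, and 8456 for differences among wild-type lines. Without the 2 discordant libraries (46 arrays) there were 85 and 33 in untreated knockouts of XBP1 and ATF4. The 37 arrays gave 7740 and 6186 in wild type at 12 h and 24 h, 777 interval features at 12 h, 30 for 24 h against 12 h, 1221, 1387, 339 and 717 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 67, 1385, 98 and 152 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, 19, 266 and 131 in 24 h dependences on XBP1, ATF4 and ATF6a, 27585 over the responses of single lines, 11237 for knockout against wild type after treatment, and 1199 for differences among wild-type lines. Relative to the median, the wild-type responses changed their split: the median shift gave 569 higher and 1295 lower at 12 h (the median of all features moved by -1.24) and 611 and 1393 at 24 h, and quantile normalization 140 and 356, and 178 and 485. The deposited value table gave 3191 higher and 3694 lower at 12 h, and 3227 and 3580 at 24 h.

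The following are the same for the 37 arrays. At an adjusted p under 0.01 there were 4572 and 3252 in wild type at 12 h and 24 h, 410 and 176 interval features, 16 for 24 h against 12 h, 627, 655, 168 and 274 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 12, 279, 54 and 37 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, 1, 21 and 54 in 24 h dependences on XBP1, ATF4 and ATF6a, and 267 for differences among wild-type lines. An added limit of at least 2-fold left 3861 and 3556 in wild type at 12 h and 24 h, and 466 and 348 interval features. Normexp correction gave 67 for 24 h against 12 h, and 37 in the 12 h dependence on XBP1. Under quantile normalization there were 317 in the 12 h dependence on ATF6b, and 51 in the 24 h dependence on XBP1. A median shift left 10 for 24 h against 12 h, 12, 583, 46 and 63 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, 2, 96 and 65 in 24 h dependences on XBP1, ATF4 and ATF6a, and 564 for differences among wild-type lines. The deposited value table gave 101 and 361 in 12 h dependences on XBP1 and ATF6b, and 46 in the 24 h dependence on XBP1. No filter on dim probes left 27 and 836 in 12 h dependences on XBP1 and ATF4, and 137 in the 24 h dependence on ATF4. Only probes above background on all arrays, which are fewer, left 352 and 239 interval features, 643, 580, 135 and 386 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, and 40 and 62 in 12 h dependences on XBP1 and ATF6a. The mean of all tested probes gave 104 for 24 h against 12 h, 170 and 286 in 12 h dependences on ATF6a and ATF6b, and 30 in the 24 h dependence on XBP1. Trend and robust in eBayes gave 425 in the 24 h dependence on ATF4. Without the mask of local patches there were 491 for 24 h against 12 h, 334 and 307 in 12 h dependences on ATF6a and ATF6b, 211 in the 24 h dependence on ATF6a, and 2203 for differences among wild-type lines. The mask of local patches at the higher limit of 1 gave 54 for 24 h against 12 h. A replicate block gave 56 for 24 h against 12 h, 2199, 150 and 362 in 12 h dependences on ATF4, ATF6a and ATF6b, 36 and 439 in 24 h dependences on XBP1 and ATF4, and 1967 for differences among wild-type lines. A replicate block within mediator gave 2167 and 361 in 12 h dependences on ATF4 and ATF6b, and 426 in the 24 h dependence on ATF4. As a fixed block, run gave 96 for 24 h against 12 h, 1974, 2129, 547 and 1341 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 141, 2864, 233 and 564 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, and 48, 693 and 240 in 24 h dependences on XBP1, ATF4 and ATF6a. As a random block, with a consensus correlation of 0.245, run gave 75 for 24 h against 12 h, 1995, 2107, 572 and 1374 in untreated knockouts of XBP1, ATF4, ATF6a and ATF6b, 155, 2909, 218 and 530 in 12 h dependences on XBP1, ATF4, ATF6a and ATF6b, and 73, 795 and 264 in 24 h dependences on XBP1, ATF4 and ATF6a. The replicate block changed no other count of either set by more than 1.5 times. Camera called 11 of the 135 list tests with estimated correlation on the 48 arrays and 31 of the 146 on the 37.

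Of 466 results of single genes named on the 37 arrays, 442 kept their direction and side of the threshold with the deposited value table, 444 with quantile normalization, 405 with normexp, 375 with the median shift, 404 without the filter, 453 with the mean of probes, 465 with the replicate block, 455 with run as a random block, and 466 both without the mask and with its higher limit. With probes above background on all arrays 233 did and 2 reversed, and the others gave no value. On 40, 46 and 48 arrays 301, 121 and 118 did, and of the rest 1 reversed in each. The reversed results were the following, and the cause was not tested. The deposited value table gave 0.1 for Crybb3 and 0.6 for Tmem253 in the ATF6a dependence at 12 h. Probes above background on all arrays gave 2.79 for Gas1 in the ATF6b dependence at 12 h and -0.39 for Tmem41b in the untreated ATF4 knockout. Xbp1 in the untreated XBP1 knockout, which did not pass, had -0.044 with quantile normalization and 0 with the deposited value table. Serp1 in wild type at 24 h, 1.36 ± 0.15 on the 37 arrays, had -0.96 on 40 arrays and -0.50 on 46 and 48.

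Leaving out 1 array of the 48 at a time gave these ranges, with each array named that moved a count by more than 1.5 times. Each array of ATF4 dependence at 12 h moved its count of 1, to 0 throughout. ATF4 dependence at 24 h (0) ranged over 0 to 1, with 1 without ATF4 wild type 24 h replicate 1. Each array of the untreated ATF4 knockout moved its count of 14, to 0 to 1. ATF6a dependence at 24 h (0) ranged over 0 to 1, with 1 without ATF6a knockout 24 h replicate 2 and 1 without ATF6a wild type 24 h replicate 2. Each array of the untreated ATF6a knockout moved its count of 4, to 0 to 1. ATF6b dependence at 24 h (0) ranged over 0 to 1805, with 1805 without ATF6b wild type 24 h replicate 1. Each array of the untreated ATF6b knockout moved its count of 14, to 0 throughout. XBP1 dependence at 24 h (0) ranged over 0 to 3, with 3 without XBP1 knockout 24 h replicate 1. The untreated XBP1 knockout (51) ranged over 6 to 12, with 12 without XBP1 knockout untreated replicate 1, 10 without XBP1 knockout untreated replicate 2, 6 without XBP1 wild type untreated replicate 1 and 9 without XBP1 wild type untreated replicate 2. Differences among the wild-type lines (0) ranged over 0 to 1431, with 1 without ATF4 wild type 24 h replicate 1, 7 without ATF6a wild type 12 h replicate 1, 1 without ATF6a wild type 12 h replicate 2, 1 without ATF6a wild type 24 h replicate 2 and 1431 without ATF6b wild type 24 h replicate 1. Interval features at 12 h (285) ranged over 125 to 504, with 125 without ATF4 wild type 12 h replicate 2, 161 without ATF4 wild type untreated replicate 2, 148 without ATF6a wild type 12 h replicate 1, 504 without ATF6a wild type 12 h replicate 2, 186 without ATF6a wild type untreated replicate 2, 129 without ATF6b wild type 12 h replicate 1, 492 without ATF6b wild type 12 h replicate 2, 169 without XBP1 wild type 12 h replicate 1 and 155 without XBP1 wild type untreated replicate 1. Interval features at 24 h (412) ranged over 183 to 855, with 230 without ATF4 wild type 24 h replicate 2, 244 without ATF4 wild type untreated replicate 2, 183 without ATF6a wild type 24 h replicate 1, 855 without ATF6a wild type 24 h replicate 2, 260 without ATF6a wild type untreated replicate 2, 274 without ATF6b wild type untreated replicate 1, 202 without XBP1 wild type 24 h replicate 2 and 244 without XBP1 wild type untreated replicate 1. Wild type at 12 h (2024) ranged over 955 to 2938, with 955 without ATF4 wild type 12 h replicate 2, 1203 without ATF4 wild type untreated replicate 2, 1305 without ATF6a wild type 12 h replicate 1, 1311 without ATF6a wild type untreated replicate 2, 1080 without ATF6b wild type 12 h replicate 1, 1311 without ATF6b wild type untreated replicate 1, 1220 without XBP1 wild type 12 h replicate 1 and 1126 without XBP1 wild type untreated replicate 1. The count for 24 h against 12 h (0) ranged over 0 to 593, with 1 without ATF4 wild type 24 h replicate 1, 1 without ATF6a wild type 24 h replicate 2 and 593 without ATF6b wild type 24 h replicate 1. Wild type at 24 h (2883) ranged over 1423 to 5405, with 1713 without ATF4 wild type 24 h replicate 2, 1816 without ATF4 wild type untreated replicate 2, 1423 without ATF6a wild type 24 h replicate 1, 5405 without ATF6a wild type 24 h replicate 2, 1857 without ATF6a wild type untreated replicate 2, 1884 without ATF6b wild type untreated replicate 1, 1511 without XBP1 wild type 24 h replicate 2 and 1805 without XBP1 wild type untreated replicate 1. The 12 h dependences on ATF6a, ATF6b and XBP1 did not move.

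The same on the 37 arrays, where an array could be left out only if its group kept 1, gave the following. ATF4 dependence at 12 h (1385) ranged over 305 to 1778, with 531 without ATF4 knockout 12 h replicate 1, 726 without ATF4 knockout 12 h replicate 2, 305 without ATF4 knockout untreated replicate 2, 446 without ATF4 wild type 12 h replicate 1, 773 without ATF4 wild type 12 h replicate 2, 793 without ATF4 wild type untreated replicate 1 and 461 without ATF4 wild type untreated replicate 2. ATF4 dependence at 24 h (266) ranged over 34 to 585, with 585 without ATF4 knockout untreated replicate 1, 34 without ATF4 knockout untreated replicate 2, 40 without ATF4 wild type 24 h replicate 2, 173 without ATF4 wild type untreated replicate 1 and 36 without ATF4 wild type untreated replicate 2. The untreated ATF4 knockout (1387) ranged over 618 to 924, with 924 without ATF4 knockout untreated replicate 1, 737 without ATF4 knockout untreated replicate 2, 618 without ATF4 wild type untreated replicate 1 and 894 without ATF4 wild type untreated replicate 2. ATF6a dependence at 12 h (98) ranged over 64 to 109, with 64 without ATF6a wild type untreated replicate 1. ATF6a dependence at 24 h (131) ranged over 87 to 111, with 87 without ATF6a wild type untreated replicate 1. The untreated ATF6a knockout (339) ranged over 195 to 284, with 195 without ATF6a wild type untreated replicate 1. ATF6b dependence at 12 h (152) ranged over 84 to 196, with 84 without ATF6b knockout untreated replicate 2. The untreated ATF6b knockout (717) ranged over 233 to 974, with 312 without ATF6b knockout untreated replicate 1, 264 without ATF6b knockout untreated replicate 2 and 233 without ATF6b wild type untreated replicate 2. XBP1 dependence at 12 h (67) ranged over 16 to 51, with 26 without XBP1 knockout 12 h replicate 1, 27 without XBP1 knockout 12 h replicate 2, 38 without XBP1 knockout untreated replicate 2, 16 without XBP1 wild type 12 h replicate 1, 26 without XBP1 wild type 12 h replicate 2, 18 without XBP1 wild type untreated replicate 1 and 38 without XBP1 wild type untreated replicate 2. XBP1 dependence at 24 h (19) ranged over 1 to 31, with 31 without XBP1 wild type 24 h replicate 1, 1 without XBP1 wild type 24 h replicate 2, 1 without XBP1 wild type untreated replicate 1 and 4 without XBP1 wild type untreated replicate 2. The untreated XBP1 knockout (1221) ranged over 641 to 1011, with 641 without XBP1 wild type untreated replicate 1 and 781 without XBP1 wild type untreated replicate 2. Differences among the wild-type lines (1199) ranged over 681 to 1350, with 681 without ATF4 wild type untreated replicate 2, 787 without ATF6a wild type untreated replicate 1 and 777 without XBP1 wild type untreated replicate 1. Interval features at 24 h (524) ranged over 308 to 540, with 332 without ATF4 wild type 24 h replicate 2 and 308 without XBP1 wild type 24 h replicate 2. The count for 24 h against 12 h (30) ranged over 18 to 28, with 18 without ATF4 wild type 12 h replicate 1 and 18 without XBP1 wild type 24 h replicate 2. Ranges without such an array were interval features at 12 h 645 to 838, wild type at 12 h 6701 to 7684 and wild type at 24 h 4686 to 5987. In these fits the lone array of a group is assumed to vary like the other groups.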

Other observations

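The average over knockout lines, and the set of 37 arrays, were chosen only after the data were seen, while the tests of other divisions were set before their results. The knockout lines still answered tunicamycin. Over the knockout lines at 12 h, 6584 of 23488 features passed on the 37 arrays, 3839 higher and 2745 lower, and 1710 on the 48. Of 28 ER chaperones and folding enzymes 21 rose and 2 fell (camera adjusted p = 6.92e-14, and 0.0133 with an estimated correlation), as did 14 of 26 degradation genes and 12 of 24 amino acid genes. Ddit3 (3.34 ± 0.29) and Car6 (at least 16.0-fold) were among the genes that rose, and the interval features on chromosome 5 rose here as well. Cholesterol synthesis had 20 of 23 lower (0.354 with an estimated correlation), and 10 of 12 contractile and 11 of 25 matrix markers fell. These values average over lines with different deletions, and whether they differ from wild type was tested only within each mediator.

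Within each line, the arrays of the 2 compared groups were divided in other ways to see how many features chance divisions would call. On the 48 arrays the real division gave 2024 features at 12 h (highest other 1271), 285 interval features (208), 2883 at 24 h (1226) and 412 interval features (174). In each case only 1 of 100 divisions, the real one, gave as many. That is the lowest share possible, since the real division was among the 100. On the 37 arrays the values were 7740 (3790), 777 (435), 6186 (3510) and 524 (209), again 1 of 100 each. These divisions do not part treatment from run, which were confounded. For 24 h against 12 h chance cannot be excluded on the 37 arrays, where 30 of 36 divisions gave at least the real 30, with 85 the highest other. These divisions mix runs. With run as a fixed block 96 features passed, and 14 of 16 divisions that exchange the 2 times only within a line and run, chosen after the result was seen, gave at least as many (highest other 179). Even a real division that stood alone would have had a share of 0.0625. On the 48 arrays limma called 0 (458 at an unadjusted p under 0.05), so all 100 of 100 divisions had to give as many, which decides nothing, and the highest gave 15130. Divisions that call many more features point to a structure of the samples, and the 2 replicates of the treated groups were on different runs.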
